A study of Mus musculus with 20 samples.

How the data were processed

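Peak lists of 10 immunoprecipitated libraries were used: pRb (for which the labels list 5 antibodies) and H3K27me3 in arrested and proliferating WT and SS fibroblasts, and Ezh2 in serum-deprived WT and SS fibroblasts. Groups were taken from the sample titles. Per the labels' protocols, chromatin was cross-linked with a long-arm linker and formaldehyde and sheared by sonication. Per the submitters' processing notes the tools were Bowtie2, MACS2, HOMER and bedtools, and the genome build was mm9, with no versions, roles or settings. Peaks were called per library, since each library has its own list; the control used and the settings are not given in the sources used here. A library with more reads yields more and weaker peaks, and lists called with different settings differ in peak length. Both can move every number that depends on list size, and neither can be corrected from the lists.

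The 4 deposited pRb lists hold a score per peak in 5 columns. Their lowest score is 20, and no header states the unit. The other 6 deposited lists have 9 columns in the layout of MACS2 broad peaks: a score, the fold enrichment over background as a ratio, the -log10 p-value and the -log10 q-value as the authors' caller gave them. In all rows the score was 10 times the -log10 q-value cut to a whole number. In what follows, the authors' score is the -log10 q-value for these 6 lists and the score column for the 4 pRb lists. Such scores were used to rank or filter peaks within a list. The exception is the common cutoff, an alternative fixed beforehand that applies 1 threshold to both lists and so carries any difference in depth or settings. No count of reads was used, so the depth per sample is unknown and no interval based on depth is given.

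Positions were kept in mm9 as deposited and are printed counted from 1. The gene table used for symbols belongs to another assembly, so no peak was assigned to a gene, the gene lists prepared for promoters were not used, and repeat content was not analysed here. In place of genes, the rule fixed before the data were examined names, for each comparison, the 5 bins of 100 kb with the largest gain and the 5 with the largest loss of covered share, and the 3 peaks of highest authors' score in each library; the leading ones are described. The longest peaks and domains lie outside the rule.

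Covered length is the summed length of the peaks, which do not overlap within a list. Lists were compared by the share of peaks with at least 1 bp in a peak of the other list. This share was divided by the mean of 20 random placements, which kept each peak's chromosome and length and drew positions from the 25686 bins of 100 kb in which any list had a peak (seed 1). Placement did not account for mappability or open chromatin within bins, so folds are set beside those of pairs of different antibodies. Shares have Wilson 95% intervals. Spearman correlations used 24020 autosomal bins. Domains are the merged peaks over 10 kb of either proliferating H3K27me3 list. A list that defines domains covers them by construction: with domains from the proliferating WT list alone, WT peaks covered 100% of every domain and SS peaks covered more in 0%. Domain coverage was therefore compared between the arrested lists only, although it had first been computed for the other pairs too.

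The overlap step was tested on simulated lists. Their peaks were placed by the same random placement, so the test checks the computation and not clustering or mappability. With no planted sharing, the excess over random placement ranged from -0.182% for proliferating H3K27me3 to 0.0290% for Ezh2. The folds there ranged from 0.960 for proliferating pRb to 1.00 for Ezh2. With 20% planted, the step recovered 19.1% for arrested pRb, 19.9% for proliferating pRb and 19.1% for Ezh2. It recovered 17.9% for arrested H3K27me3 and 17.8% for proliferating H3K27me3. Alternatives fixed beforehand were the common score cutoff, merging of peaks within 1 kb, autosomes only, a reciprocal overlap of 50%, equal list lengths and the higher-scoring part of each list. Others were added after the data were seen. With 1 library per group no test across samples was made. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.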

Results

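Chromatin immunoprecipitation followed by sequencing was carried out on mouse embryonic fibroblasts, primary cells taken from C57BL/6 embryos at stage E13.5 and grown to passage 4. Wild-type cells (WT) were set beside cells of a mutant genotype that the labels call SS and do not spell out. The proteins assayed were pRb, the retinoblastoma tumour suppressor, Ezh2, the catalytic subunit of Polycomb repressive complex 2, and the histone mark H3K27me3, which that complex deposits. pRb and H3K27me3 were assayed in arrested and in proliferating cells, and Ezh2 in serum-deprived cells. The series title links the tumour suppressor to silencing of endogenous retroelements. Each of the 10 immunoprecipitated libraries gave 1 peak list, and each combination of antibody, growth condition and genotype had 1 library. No difference below therefore has a replicate check, and no p-value is given. The sequencing depth of the libraries is unknown from the peak lists, and the 10 input libraries were not analysed here. For arrested pRb libraries the labels name arrest by confluence in one field and 0.1% serum for 72 h in another, whereas the H3K27me3 and Ezh2 labels name serum deprivation in both.

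The lists differed widely in size and in the kind of peak they held. The pRb lists held 424588 peaks in arrested WT cells, 650383 in arrested SS cells, 77809 in proliferating WT cells and 106472 in proliferating SS cells. Ezh2 had the most peaks, 840543 in WT and 1184135 in SS cells, of which 62.0% and 58.5% had the shortest length in their list, 50 and 51 bp. In the arrested WT H3K27me3 list, 46.0% of the 656342 peaks had the shortest length of 133 bp. Peaks over 10 kb were found in H3K27me3 lists alone: 3420 in proliferating WT, 4000 in proliferating SS, 633 in arrested SS and 6 in arrested WT cells. The 2 longest peaks lay on chromosome 15 of the mm9 build, at 102702120-102909341 in proliferating SS cells and at 102723644-102908613 in proliferating WT cells. These longest peaks were chosen after their values were seen.

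**Figure D1:**
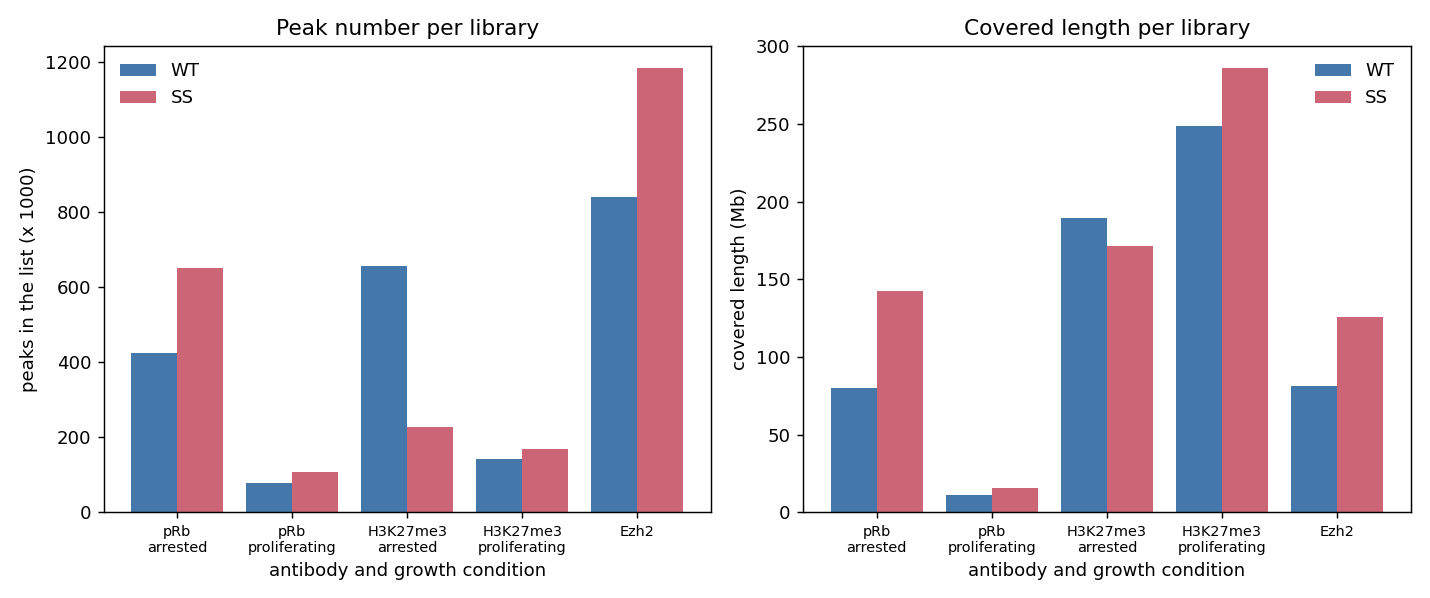
Number of peaks (left, axis scaled as labelled) and length covered by peaks (Mb, right) in each of the 10 libraries, 1 library per bar, with WT and SS side by side. SS bars are higher than WT bars for pRb, Ezh2 and proliferating H3K27me3, and lower for arrested H3K27me3, where the peak number was 656342 in WT and 227847 in SS cells.

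The first comparison asked how the extent of each protein or mark differed between genotypes. SS lists held more pRb peaks than WT lists, by 1.53 times in arrested and 1.37 times in proliferating cells, and covered 1.77 and 1.36 times the length. For Ezh2 the peak number was 1.41 times and the covered length 1.54 times that of WT. H3K27me3 covered 285.9 Mb in proliferating SS and 248.3 Mb in proliferating WT cells, a ratio of 1.15, with 1.18 times as many peaks. In arrested cells the SS list held 0.347 times as many H3K27me3 peaks as the WT list and covered 0.904 times the length. Counting only peaks of at least 500 bp, a setting chosen after the data were seen, brought the arrested H3K27me3 ratio to 0.941 and raised that of arrested pRb to 4.14 and that of Ezh2 to 2.79. At a common cutoff on the authors' score the arrested H3K27me3 ratio was 0.00349, with 1536 SS peaks left against 440559 WT peaks, and the covered length ratio 0.00689. There the peak number ratio was 2.03 for proliferating H3K27me3 and 2.89 for Ezh2, whose covered length ratio was 3.26.

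H3K27me3 was arranged in broad autosomal domains, defined as the merged peaks over 10 kb of the proliferating lists. There were 4359 such domains covering 85.3 Mb. Peaks of the arrested lists, which took no part in the definition, covered 33.1% of the domain sequence in WT and 61.8% in SS cells, against 6.76% and 4.61% elsewhere on the autosomes. Arrested SS peaks covered more than arrested WT peaks in 4134 of the 4359 domains, with a median difference of 27.7 percentage points. At the common score cutoff, which left few SS peaks, they covered more in 0.344% of domains. The authors' fold enrichment per peak had a median of 5.85 in the arrested WT list and 3.24 in the arrested SS list, and such values were not compared further between lists. The longest domain, on chromosome 11 at 96005560-96248997, was covered to 47.6% in arrested WT and 64.9% in arrested SS cells. On chromosome 8 at 125185249-125299240 the shares were 39.3% and 89.3%. These domains were chosen after their values were seen. pRb and Ezh2 peaks showed little preference for the domains: Ezh2 coverage was 1.05 times that elsewhere in both genotypes, and pRb coverage between 1.01 and 1.14 times.

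**Figure D2:**
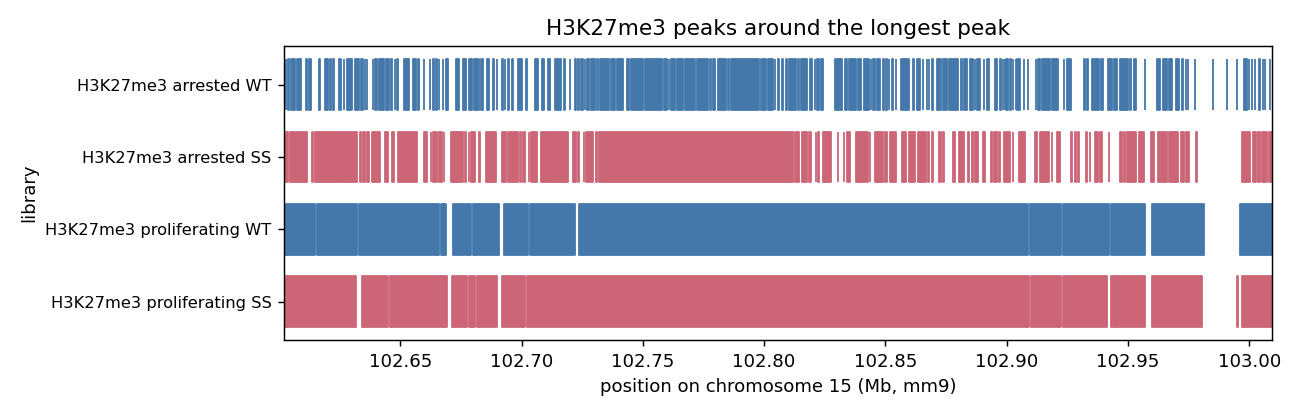
H3K27me3 peaks in the 4 libraries around the longest single peak, on chromosome 15 (position in Mb, mm9), each box being a called peak and each line a library. Proliferating lists show nearly continuous peaks, whereas arrested lists show the same region in more and shorter pieces.

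Among the 100 kb bins with the largest genotype differences in H3K27me3, the X chromosome held losses in proliferating and gains in arrested SS cells. In proliferating cells the 5 bins of largest loss in SS were all on X, led by the bin at 92100001-92200000, covered to 76.5% in WT and listed at 0 in SS cells. In arrested cells the same bin led the gains, with 6.47% covered in WT and 62.4% in SS cells, and 4 of the 5 largest gains were on X. None of the 5 largest losses in arrested cells or the 5 largest gains in proliferating cells was on X. Summed over the X chromosome, SS covered 2.48 times the WT length in arrested cells and 0.155 times in proliferating cells. Relative to the autosomes, the share of X covered was 0.387 times as high in arrested WT, 1.11 times in arrested SS, 0.829 times in proliferating WT and 0.107 times in proliferating SS cells. The Y chromosome held 351, 0, 0 and 38 H3K27me3 peaks in the same 4 libraries. On the autosomes the largest gain in arrested SS cells was on chromosome 8 at 125200001-125300000, from 39.4% to 88.1%, and the largest gain in proliferating SS cells was on chromosome 6 at 114500001-114600000, from 11.8% to 60.2%. The largest autosomal losses were smaller, from 26.6% to 9.05% on chromosome 8 at 73600001-73700000 in arrested cells and from 43.0% to 20.1% on chromosome 9 at 46800001-46900000 in proliferating cells.

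**Figure D3:**
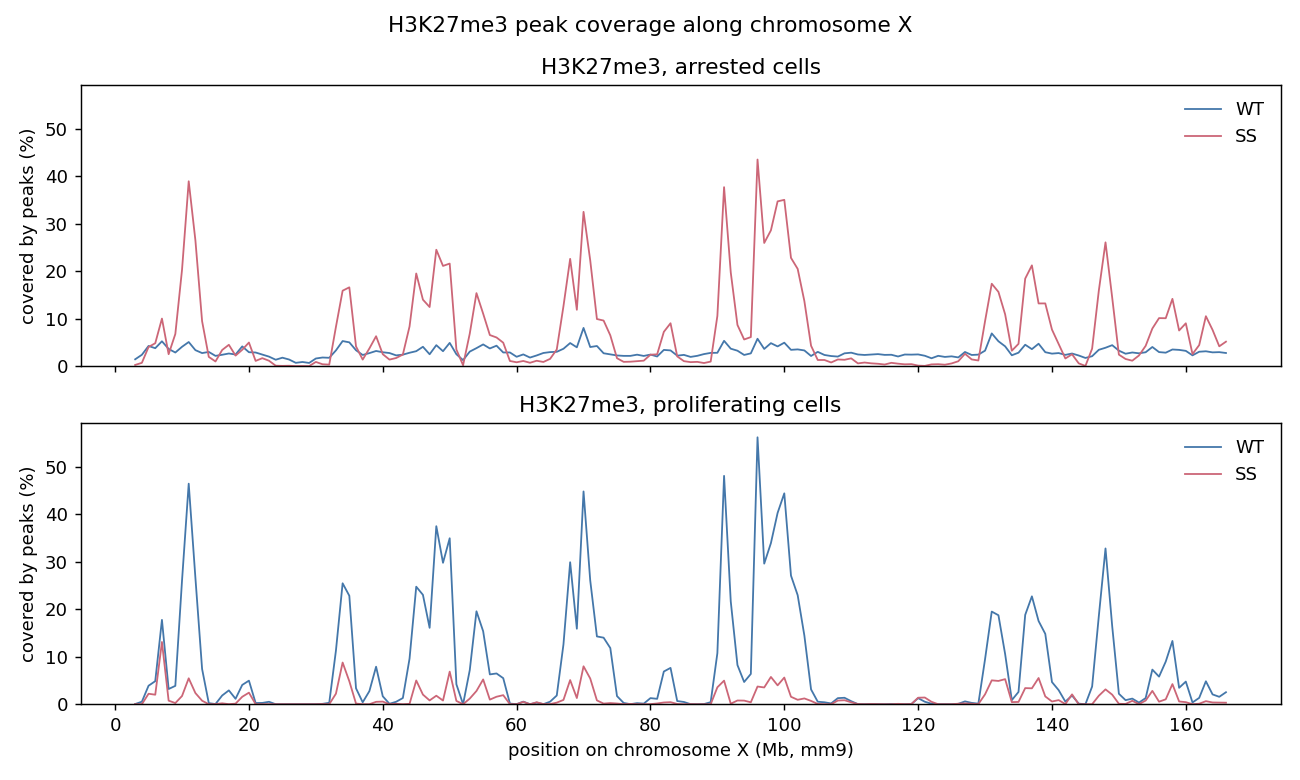
Share of the X chromosome covered by H3K27me3 peaks (%) in steps of 1 Mb along the chromosome (Mb, mm9), for arrested cells (top) and proliferating cells (bottom), 1 line per library. In arrested cells the SS line rises above the WT line in blocks, in 87 of 164 steps, and lies below it in the other 77, whereas in proliferating cells the WT line was higher in 136 steps and the SS line in 15.

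For arrested pRb the largest gain in SS was on the Y chromosome at 2800001-2900000, from 0.529% to 35.9%, and the largest loss on chromosome 5 at 95500001-95600000, from 11.6% to 5.21%. For proliferating pRb the largest gain was on chromosome 6 at 47600001-47700000, from 0.453% to 6.99%, and the largest loss on chromosome 5 at 15000001-15100000, from 4.62% to 0.311%. For Ezh2 the largest gain was on chromosome 7 at 46500001-46600000, from 8.21% to 21.1%, and the largest loss on the same chromosome at 39100001-39200000, from 12.1% to 8.48%. Genes and repeat families in these bins were not analysed here, because no annotation of the mm9 build was used. The Y bin and those at 15000001-15100000 on chromosome 5 and 46500001-46600000 on chromosome 7 recurred among the most covered of the pRb and Ezh2 lists. Ezh2 peaks covered the Y bin to 27.1% in WT and 30.8% in SS cells. The arrested pRb lists held 40 Y peaks in WT and 202 in SS cells, but their X coverage relative to autosomes was similar, 0.864 and 0.797. X and Y thus did not split together there, and the source of the Y difference, whether genotype, sex of the cultures or another, was not settled.

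The next comparison asked whether the peaks of the 2 genotypes lay in the same places. H3K27me3 peaks did so in proliferating cells: 63.8% of WT peaks (95% Wilson interval 63.6 to 64.1) shared at least 1 bp with an SS peak, against 18.3% after random placement, a fold of 3.49. In arrested cells 15.9% of WT H3K27me3 peaks overlapped an SS peak, 1.74 times the random share. The arrested WT list stood apart from the other H3K27me3 lists in both genotypes: its peaks overlapped proliferating WT and SS peaks at 1.80 and 1.73 times the random share, whereas arrested SS peaks did so at 3.37 and 3.14 times. For Ezh2 the share of WT peaks that overlapped an SS peak was 11.3%, or 1.20 times random placement. For pRb it was 11.0% and 1.07 times in arrested cells, and 1.74% and 1.39 times in proliferating cells. The 64 ordered pairs of lists from different antibodies gave folds of 1.06 to 1.17. Among the 500 peaks of highest authors' score in each list, 80.8% of proliferating WT H3K27me3 peaks overlapped the matching SS set. The same share was 10.0% (7.67 to 12.9) for Ezh2, 0.6% for pRb in either growth condition and 0.2% for arrested H3K27me3. Between antibodies, 6.0% (4.23 to 8.44) of either Ezh2 set overlapped the arrested SS H3K27me3 set and 0.4% the arrested WT set. No random placement stands beside these shares. Over the full lists, WT and SS Ezh2 peaks overlapped arrested SS H3K27me3 peaks at 1.13 and 1.11 times random placement. With arrested WT H3K27me3 peaks the fold was 1.10 for either list, so all lay within the range of different antibodies. An Ezh2 SS peak of rank 3, on chromosome 14 at 104736163-104736302, lay in an arrested SS H3K27me3 peak of rank 2, and 6 other lists had a peak there. Of the arrested SS H3K27me3 set, 20 and 22 of the 500 peaks overlapped the proliferating WT and SS sets and 1 the arrested WT set. Among the 5000 highest, the share of WT peaks in the matching SS set was 73.5% for proliferating H3K27me3, 1.84% for Ezh2 and 0.30% for proliferating pRb. It was 0.26% for arrested H3K27me3 and 0.12% for arrested pRb. At that size 0.98% of the WT and 1.00% of the SS Ezh2 set overlapped the arrested SS H3K27me3 set. Across 24020 autosomal bins, which are not independent replicates, Spearman's rho between genotypes was 0.949 for proliferating H3K27me3, 0.805 for arrested H3K27me3, 0.468 for Ezh2, 0.135 for proliferating pRb and 0.0444 for arrested pRb. The 32 pairs of lists from different antibodies gave rho from -0.165 to 0.223, a range that holds both pRb values. Intervals cover counting error over peaks only, and neighbouring peaks are not independent.

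**Figure D4:**
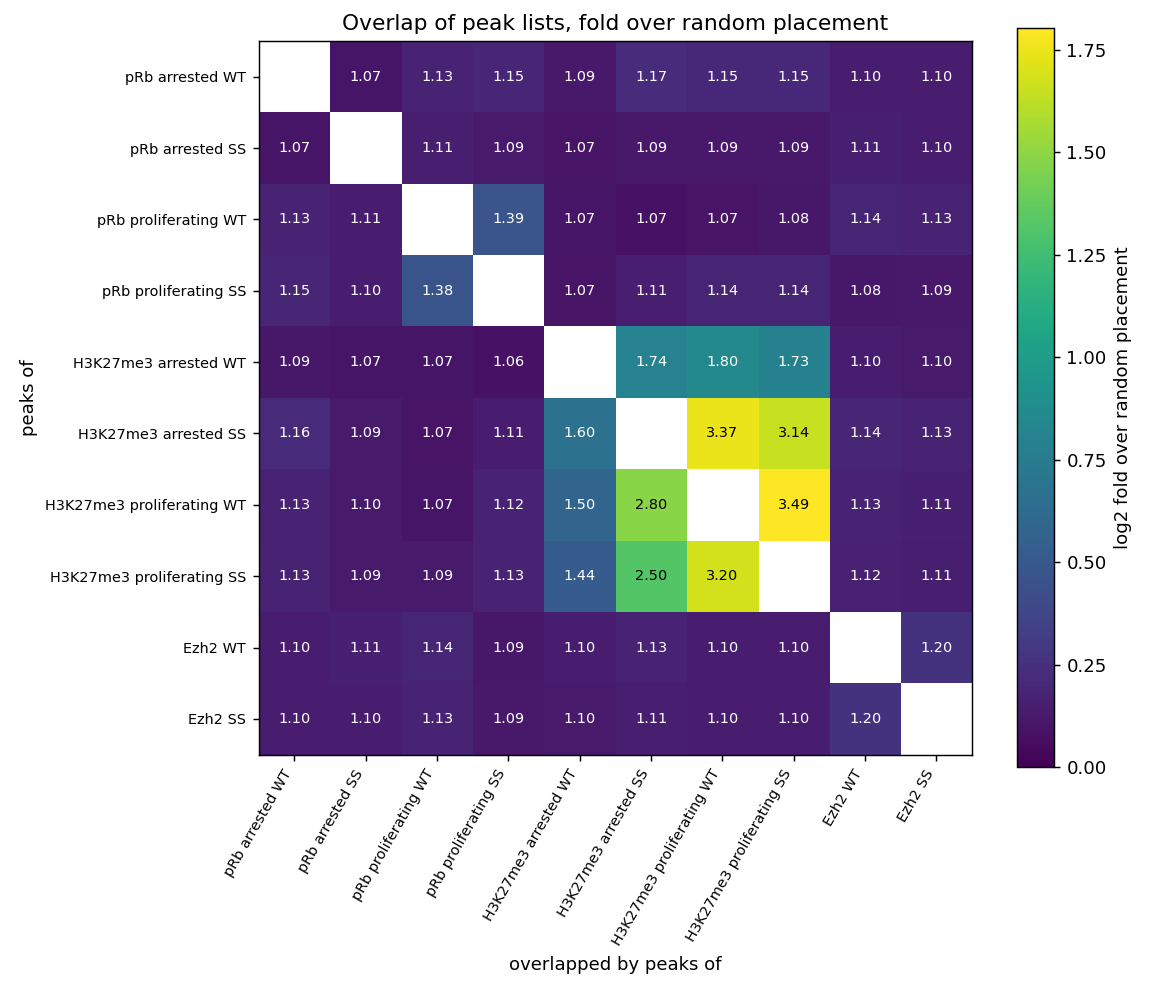
Overlap of each list (row) with each other list (column), as a fold over random placement on the same chromosomes, for the 10 libraries, with the colour on a log2 scale. The H3K27me3 block holds the highest folds, up to 3.49, while pairs of different antibodies lie between 1.06 and 1.17.

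Of the 500 peaks of highest authors' score in a pRb list, 0 to 4 overlapped the 500 highest in an Ezh2 list, a share with no random placement beside it. A peak on chromosome 1 at 24618291-24623103 led the arrested WT pRb list, and an overlapping peak had the second highest score in the proliferating WT list. In the arrested SS list an overlapping peak was 1 of 4 tied at the highest score of 3100. In both Ezh2 lists the highest score fell on chromosome 6, at 103599055-103599265 in WT and 103599063-103599266 in SS cells. The arrested pRb lists had a peak at the same place, at 103598728-103599371 in WT and, among the 4 tied, at 103598955-103599385 in SS cells. The proliferating SS pRb list was led by a peak on chromosome 2 at 98502361-98503182, where none of the other lists had a peak. The same held for its peaks ranked 2 and 3, on chromosome 12 at 3109860-3110198 and chromosome 2 at 98506336-98507498. Whether the leading peaks named here mark binding or arise from mapping was not tested. Absence from the other lists may also reflect how each list was processed.

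Arrested and proliferating cells were then compared within each genotype. pRb peaks were 5.46 times as many in arrested as in proliferating WT cells and 6.11 times as many in SS cells. At the common score cutoff 15 proliferating WT and 111 proliferating SS pRb peaks were left, so that the ratios rose to 20167 and 3617. H3K27me3 peaks were 4.58 times as many in arrested WT cells, while the covered length was 0.764 times that of proliferating cells. The WT peak number ratio was 172 at the common cutoff and 1.17 among peaks of at least 500 bp. In SS cells the peak number was 1.35 times and the covered length 0.600 times that of proliferating cells, and the peak number ratio fell below 1 at the common cutoff (0.752) and among peaks of at least 500 bp (0.959). On X, the covered length was 0.367 times in WT and 5.87 times in SS cells. In WT cells the largest loss of called H3K27me3 coverage, arrested against proliferating, was on chromosome 15 at 101600001-101700000, from 94.7% to 23.5%. The arrested WT list held 6 peaks over 10 kb against 3420 in the proliferating WT list, and called coverage is not the amount of the mark. In SS cells the largest loss was on chromosome 11 at 96400001-96500000, from 86.0% to 22.6%, while the 5 largest gains were all on X. The arrested SS list held 0 Y peaks and the proliferating SS list 38. For pRb the largest gain of coverage in arrested WT cells was on chromosome 5 at 14900001-15000000, from 5.48% to 21.1%. In arrested SS cells it was on chromosome 1 at 85200001-85300000, from 1.59% to 31.6%. Both bins also recurred among the most covered of the pRb and Ezh2 lists.

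The last comparison asked whether pRb peaks in arrested cells coincided with Ezh2 or H3K27me3. In WT cells 10.3% of pRb peaks overlapped an Ezh2 peak and 13.3% an H3K27me3 peak, which was 1.10 and 1.09 times random placement. In SS cells the shares were 16.4% and 9.36%, again 1.10 and 1.09 times random placement. These folds lay within the range of 1.06 to 1.17 of all pairs of different antibodies, of which they are part. Lists of unlike genotype gave similar folds. WT pRb peaks overlapped SS Ezh2 and arrested SS H3K27me3 peaks at 1.10 and 1.17 times random placement. SS pRb peaks overlapped WT Ezh2 and arrested WT H3K27me3 peaks at 1.11 and 1.07 times. The excess was therefore not particular to matched lists. The pRb libraries and the other libraries carry different arrest labels.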

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

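The tests below were chosen after the data had been seen. All results here rest on 1 library per group, and none of the differences between groups was tested.

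H3K27me3 on the X chromosome moved in opposite directions with genotype: SS covered 2.48 times the WT length in arrested and 0.155 times in proliferating cells, and arrest went with 0.367 times the X length in WT and 5.87 times in SS cells. The mutant genotype alone, or arrest alone, would keep the ratios on the same side, but this restates the flagged pattern and is not a separate test. A difference between single libraries could also change the side. With equal list lengths the ratio of X to autosomes, SS over WT, was still 3.42 in arrested and 0.120 in proliferating cells. Cells of different sex in the compared cultures may be the source: the 2 libraries with high X coverage had 0 Y peaks, where 126 and 79.0 were expected at a haploid share of the autosomal density, and the other 2 had 92.0% and 37.8% of the number expected. The arrested pRb libraries do not follow this split: their X coverage was 0.864 and 0.797 times that of autosomes, with 16.5% and 54.2% of the expected Y peaks. Proliferating pRb libraries do, with X coverage of 0.228 and 134% and 101% of the expected Y peaks in WT and SS. So do the Ezh2 libraries, with X coverage of 0.431 and 0.464 and 115% and 122%. The embryos' sex is not in the labels used here, and an effect of genotype that depends on growth condition stays open.

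The arrested SS list of H3K27me3 peaks was 0.347 times as long as the WT list, whereas the proliferating SS list was 1.18 times as long. Among peaks of at least 500 bp the ratios were 0.941 and 1.15, so short isolated peaks in the WT list may account for most of the arrested difference in number. With the lists as called, a loss of called coverage in the broad domains goes against the values. Arrested SS peaks covered more than arrested WT peaks in 94.8% of domains, and in 96.2% of those defined from the proliferating WT list alone. The common score cutoff, which left few SS peaks, reversed this to 0.344% of domains, so the answer depends on that setting. The arrested WT library stands apart: its coverage of the domains was 4.89 times that elsewhere, against 13.4 times in arrested SS cells, and its overlap with the proliferating WT list was 1.80 times random placement, against 3.37 times for arrested SS. Called coverage is not the amount of the mark, so a change in its level stays open, as does a technical difference in either arrested library, which was not tested.

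pRb and Ezh2 peaks of WT and SS cells coincided little. For arrested pRb the fold over random placement was 1.07, inside the range of 1.06 to 1.17 given by different antibodies, which is what peaks of background reads would give. A difference in binding between genotypes could give the same fold and was not tested. The range includes pairs of pRb with Ezh2 and with H3K27me3, so it is not a pure background. For Ezh2 the fold of 1.20 and the correlation across bins of 0.468 lay above those of different antibodies (highest correlation 0.223) but its coverage of H3K27me3 domains was 1.05 times that elsewhere, and for proliferating pRb the fold of 1.39 lay above the range and the correlation of 0.135 within it. In both, background common to a pair of libraries cannot be told apart from shared sites, because the range of different antibodies does not cover it, and a difference in binding between genotypes was not tested. Without the 22 bins that recur among the most covered, the folds were 1.39 for proliferating pRb and 1.20 for Ezh2. The removal left 77587 of 77809 proliferating WT pRb peaks and 839234 of 840543 WT Ezh2 peaks, so it could move the folds only little. An excess thus remained outside those bins, but the removal was a weak test.

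Other opposite directions were seen in H3K27me3. Covered length, SS over WT, was 0.904 in arrested and 1.15 in proliferating cells, and on autosomes 0.863 and 1.21. The number of peaks of at least 500 bp in arrested over proliferating cells was 1.17 times in WT and 0.959 times in SS cells.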

How the results depend on the processing

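Of 81 alternatives to 26 results, 3 reversed the value and 38 left it within its interval (overlaps, domains) or within 1.5 times (ratios). The other 40 kept their side: 24 left the narrow interval but stayed within 1.5 times, and 16 moved by over 1.5 times. The settings with peaks of at least 500 bp, without recurrent bins, for X and for domains, and autosomes only for covered length, were chosen after seeing the data. Merging within 1 kb and autosomes only moved no ratio by over 1.5 times. Unless stated, the cause was not tested.

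At the common score cutoff the reversed results were the H3K27me3 SS peak number, arrested over proliferating (0.752), and the percent of domains with more covered in arrested SS (0.344). The SS over WT peak number became 0.00349 for arrested H3K27me3, 2.03 for proliferating H3K27me3 and 2.89 for Ezh2, and the covered length 0.00689 for arrested H3K27me3 and 3.26 for Ezh2. Arrested over proliferating peak numbers became 20167 for pRb WT, 3617 for pRb SS and 172 for H3K27me3 WT. The overlap folds of WT with SS rose to 1.14 (arrested pRb), 1.52 (proliferating pRb), 2.02 (arrested H3K27me3), 4.05 (proliferating H3K27me3) and 1.29 (Ezh2). The cutoff keeps few peaks of a list with low scores by its construction: 1536 in arrested SS H3K27me3.

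With peaks of at least 500 bp the H3K27me3 SS ratio of arrested over proliferating cells was reversed (0.959), and that of WT was 1.17. The pRb ratios were 114 in WT and 232 in SS, but they rest on only 33 WT and 67 SS proliferating peaks of that length. The SS over WT peak number was 4.14 for arrested pRb, 0.941 for arrested H3K27me3 and 2.79 for Ezh2, and X relative to autosomes in arrested H3K27me3 was 4.63.

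With a reciprocal overlap of 50% the WT with SS folds were 1.16 (arrested pRb), 1.61 (proliferating pRb), 2.31 (arrested H3K27me3), 12.3 (proliferating H3K27me3) and 1.29 (Ezh2). For pRb with Ezh2 and with H3K27me3 they were 1.16 and 1.12 in WT, and 1.17 and 1.11 in SS. In the higher-scoring part of each list these were 1.16 and 1.13 in WT, and 1.19 and 1.04 in SS. With equal list lengths the WT with SS fold was 1.92 for arrested H3K27me3, 3.59 for proliferating H3K27me3 and 1.22 for Ezh2.

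The percent of domains with more covered in arrested SS was 99.3 with equal list lengths and 99.1 for domains over 20 kb. It was 96.2 for domains of the proliferating WT list alone and 95.6 for those of the proliferating SS list alone. The same percentage between proliferating lists (65.9) is not used as a result, because the lists define the domains: it is 0 with domains of the WT list and 88.4 with those of the SS list.

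Promoter occupancy and repeat share, planned for the genotype pairs and, for promoters, for growth conditions, were not run, because no mm9 annotation or genome was used here. No paired analysis was possible because each group had 1 library. Depth is unknown, so its effect on list size was not measured.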

Other observations

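Bins of 100 kb recurred among the 50 most covered of the pRb and Ezh2 lists. Of these, 22 bins were in that set in at least 5 of the 6 lists and 9 in all 6. The bin on chromosome 5 at 14900001-15000000 was covered to 21.1% in arrested WT pRb, 27.8% in arrested SS pRb, 18.9% in WT Ezh2 and 19.4% in SS Ezh2, against median bins of 3.11%, 5.53%, 3.24% and 4.97%. The bin on chromosome 8 at 19700001-19800000 was covered to 12.6%, 31.5%, 21.0% and 23.1% in the same lists. Their repeat content was not analysed here.

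Other libraries differed on the sex chromosomes too. X coverage relative to autosomes was 0.864 in arrested WT pRb, with 40 Y peaks, and 0.797 in arrested SS pRb, with 202 Y peaks. It was 0.228 in both proliferating pRb libraries, with 62 and 64 Y peaks, and 0.431 and 0.464 in WT and SS Ezh2, with 563 and 840 Y peaks.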
